A study of Homo sapiens with 6 samples.

How the data were processed

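RNA was extracted from T3M4 cells with TRIzol, libraries were made by a sequencing company, and cells grew in DMEM with fetal bovine serum, per the labels' protocols. Samples were grouped by the guide RNA in their titles, 3 sgControl and 3 sgMETTL13 libraries. Per the submitters' processing notes the tools were HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 (no version given), and the genome builds hg38 and GRCh38.p12; the order and role of each tool are not given in the sources used here. The labels tie columns named WT to sgControl and columns named KD to sgMETTL13.

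The 1 deposited table lists 16617 genes by Entrez gene ID and symbol. Per the file headers it holds, for each group, the authors' average TPM, average FPKM and average read count, and for the comparison a log2 ratio of KD over WT with a p-value and a q-value. The averages of read counts are estimated counts (expected counts) as deposited by the authors, since 21.4% of genes have an average that is not a multiple of 1 read divided by the 3 libraries (tolerance 0.005 on the sum), which happens where reads are divided between genes. FPKM values as deposited were not used. TPM as deposited summed to 999500 in sgControl and 999463 in sgMETTL13. The deposited log2 fold change of genes at or above the median read count equals the log2 ratio of the deposited average counts plus 0.0516 (SD 0.0007 over genes), so the authors' fold changes were scaled between groups and not shrunk. Which test gave the deposited p-value is not given in the sources used here; DESeq2 is the tool in the submitters' processing notes that compares groups. The deposited q-value lies within 1.20% of a Benjamini-Hochberg adjustment of the deposited p-value, and is called the adjusted p.

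Because the table holds group averages and no value per library, no count model was fitted here. The plan fixed before the data were examined was a quasi-likelihood count model on libraries, and for a table of this kind the deposited comparison itself, with an adjusted p under 0.05, as the result. An implied standard error was computed for each gene as the size of the deposited log2 fold change divided by the normal quantile of the deposited two-sided p-value, with a 95% interval; it assumes a normal test and carries no information beyond the deposited values. The depth of single libraries is unknown, and precision is given by the implied standard error, with a median of 0.089 among genes at or above 205 mean reads and 0.574 below.

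There were 32 gene lists fixed before the data were examined, with 848 genes, of which 796 are in the table by Entrez ID, symbol or synonym; the list of mitochondrially encoded genes has none and is not analysed here, which leaves 31 lists. For each list the called members were counted over all genes and adjusted over the list alone. The list was tested with cameraPR of limma 3.58.1 (R 4.3.3) on the signed normal quantile of the deposited p-value, with a preset correlation of 0.01, and p was adjusted over the 31 lists. The median log2 fold change of the list was placed among 10000 random lists of the same size drawn from 20 bins of mean reads. Lists overlap. Among the lists called by cameraPR, SLC7A11 is in the stress response and NRF2 lists, and AREG in the RAS-ERK and basal-like lists. LDHA is in the MYC and hypoxia lists, ME1 in the fatty acid and NRF2 lists, and SLC2A1 in the hypoxia and basal-like lists. Lists that were not called also overlap, for example with TGFB2 in the TGF-beta and YAP/TEAD lists.

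The genes named in the text are METTL13, the 10 largest called rises and the 10 largest called falls among genes at or above the median read count, and up to 4 members with the smallest adjusted p of each list; genes named outside that rule are said to be so, except EEF1A1 and EEF1A2, which encode the substrate of METTL13, and members that complete a count of 5 or fewer calls or extend a list's examples (FTH1), which were chosen after their values were seen. The called members of the cholesterol synthesis list are not reported here. Coordinates, transcript GC content and transcript length come from GENCODE 29 (GRCh38), matched by Entrez ID for 16142 genes (97.1% of all genes and 99.5% of the calls). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, patsy 1.0.2 and matplotlib 3.10.9 was used.

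Alternatives were other thresholds, Bonferroni and recomputed Benjamini-Hochberg adjustments, a filter at the median read count, centred fold changes, the ratio of deposited averages, and rank-based or fold change statistics for lists. Added after the data were seen were the removal of a smooth trend (splines of 4 degrees of freedom, weighted by the implied standard error) of log2 fold change in GC content and length, the same with read count, the restriction to genes that share no reads, and a correlation of 0.1 in cameraPR. The fit of a trend has an intercept, so its removal also centres the fold changes on their weighted mean. The steps were tested on simulated data for this comparison with 16142 genes. All changed genes were drawn from those at or above the median read count, so recovery among genes with fewer reads was not tested. Of genes changed by 0.25, 0.5 and 1 on the log2 scale, 28.6%, 88.1% and 100% were recovered. Unchanged genes made up 3.92% of the calls. With an added GC trend that share was 8.81% before and 6.88% after removal of the trend. The added trend was linear in GC content, with none in length. These shares are therefore not those under the trend of the real data. In the simulation 0.5% of unchanged lists had a cameraPR p under 0.05, and 100% of shifted lists, in which every member was shifted, were called. The simulated genes were independent of each other, so the test does not show how cameraPR behaves where genes of a list are correlated.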

Results

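Messenger RNA abundance was profiled by RNA sequencing in T3M4, an established human pancreatic ductal adenocarcinoma cell line. There were 6 libraries in 2 groups, with 3 libraries from cells that received a control guide RNA (sgControl) and 3 from cells that received a guide RNA against METTL13 (sgMETTL13), which the labels call knockdown derivatives. METTL13 is a methyltransferase whose known substrate is eEF1A, the elongation factor that delivers aminoacyl-tRNAs to the ribosome. The RNA profile accompanies protein measurements of the same cells, which were not used here. The authors' deposited table holds group averages for 16617 genes together with the authors' own comparison, so the value of each library and its total are not analysed here. In the authors' deposited table the average estimated read counts summed to 15240866 per library in sgControl and 15247500 in sgMETTL13. The comparison asks which transcripts differ in abundance between sgMETTL13 and sgControl cells.

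METTL13 transcript fell 6.86-fold in the sgMETTL13 cells. In the authors' deposited table METTL13 (Entrez gene 51603) averaged 1015 estimated reads in sgControl and 142.67 in sgMETTL13, which leaves 14.1% of the reads, and its mean TPM went from 39.9 to 5.63. The log2 fold change was -2.78 in the authors' deposited table, with an adjusted p of 2.5e-127, an implied standard error of 0.114 and an implied 95% interval from -3.00 to -2.56. METTL13 is a protein-coding gene on the plus strand of chromosome 1, from 171781664 to 171814023 in GRCh38 as annotated by GENCODE 29. The transcripts of its substrate did not pass the test. In the authors' deposited table EEF1A1, the main eEF1A gene, had a log2 fold change of 0.02 (implied 95% interval from -0.10 to 0.14). EEF1A2, the other eEF1A gene, had a log2 fold change of -0.03 in the authors' deposited table (implied 95% interval from -0.25 to 0.20). Of the 6 methyltransferases known to act on eEF1A or eEF2, METTL13 was the 1 that passed the test, also adjusted over the list alone. EEF2KMT, EEF1AKMT4 and EEF1AKMT1 had log2 fold changes of -0.16, 0.16 and -0.45 in the authors' deposited table. The call of that list by cameraPR (adjusted p = 3.15e-13) rested on METTL13 and was lost in the rank-based test (adjusted p = 0.237).

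Across the transcriptome 632 of 16617 genes (3.80%) had an adjusted p under 0.05 in the authors' deposited table, 453 higher and 179 lower in sgMETTL13. Most of these changes were small. The median called rise was 0.31 on the log2 scale (1.24-fold) and the median called fall -0.38 (0.766-fold) in the authors' deposited table. In size, 14 calls of the authors' deposited table, 3 higher and 11 lower, reached a log2 fold change of 1. Among genes at or above the median of 205 mean reads there were 585 of the calls and a median implied standard error of 0.089. Among the less abundant genes there were 47 calls and a median implied standard error of 0.574, so that a change of the median size was not detectable there. Higher calls made up 71.7% of all calls. That share fell when a trend of fold change with the GC content and length of the transcript, fitted together, was removed. The removal also centred the fold changes on their weighted mean. The parts of the trend and of the centring in the fall of the share cannot be told apart. Once the trend was removed, 263 genes were higher and 170 lower, or 60.7% higher, and 217 of the 453 rises were no longer called.

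**Figure D1:**
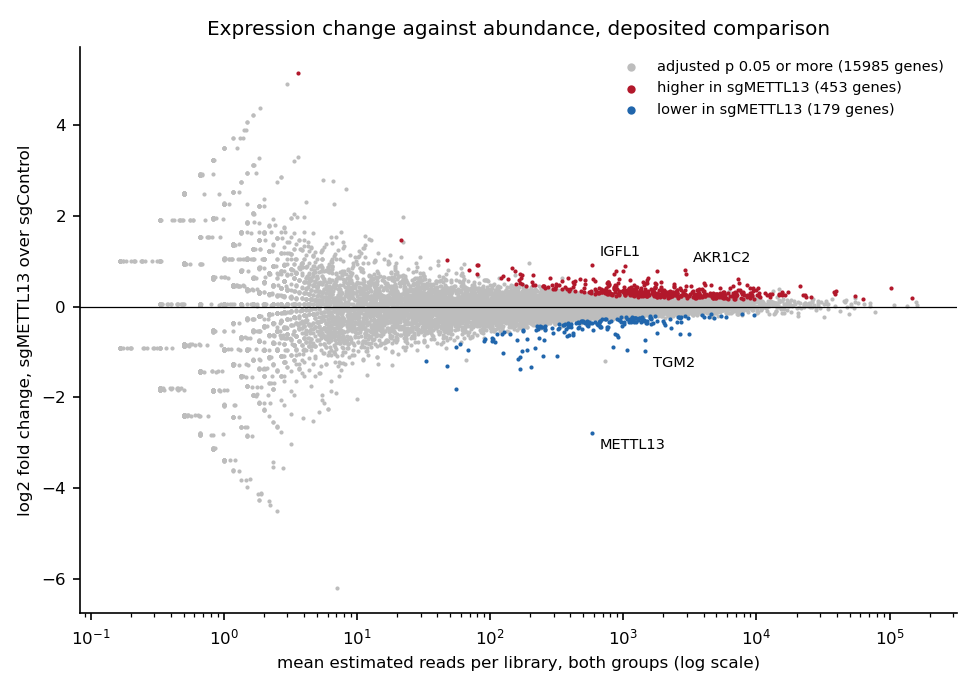
Each point is 1 of 16617 genes, with the mean estimated reads of both groups on a log axis and the log2 fold change of sgMETTL13 over sgControl in the authors' deposited table on the vertical axis; 453 called genes lie above 0 and 179 below. METTL13, at -2.78, lies below all other called genes, and the spread of uncalled genes narrows as reads increase.

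Among abundant genes the largest called rises were in IGFL1, an insulin-like growth factor family member, and SPRR1B, a cornified envelope precursor, with log2 fold changes of 0.92 and 0.89 in the authors' deposited table (1.89-fold and 1.85-fold, implied standard errors 0.095 and 0.086). The aldo-keto reductases AKR1C2 and AKR1C1 followed at 0.80 and 0.79 in the authors' deposited table, then NDUFA4L2 at 0.79, the neuronal pentraxin NPTX1 at 0.78, the AP-1 subunit FOSB and the heme oxygenase HMOX1 at 0.72 each, the kinase PIM1 at 0.69 and SLITRK6 at 0.63. After METTL13, the largest called falls were in the membrane mucin MUC16 (-1.10) and the interferon-induced IFIT1 (-1.09) in the authors' deposited table. The transglutaminase TGM2 fell to 0.510 of its control level, a log2 fold change of -0.97 in the authors' deposited table with an adjusted p of 1.97e-29, the smallest among the falls after METTL13. The remaining large falls in the authors' deposited table were MX1 (-0.96), the nucleoporin NUP210 (-0.90), OAS2 (-0.89), the siderophore-binding protein LCN2 (-0.74), the ubiquitin ligase NEURL1 (-0.73) and the epithelial sodium channel subunit SCNN1A (-0.70). The adjusted p of these 20 genes lay between 2.5e-127 and 0.0015 in the authors' deposited table. The implied standard error of MX1 was 2.88 times that of genes with the same read count. MX1 averaged 1429.56 estimated reads in sgControl and 710.25 in sgMETTL13 in the authors' deposited table. Such fractions happen where reads are divided between genes.

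**Figure D2:**
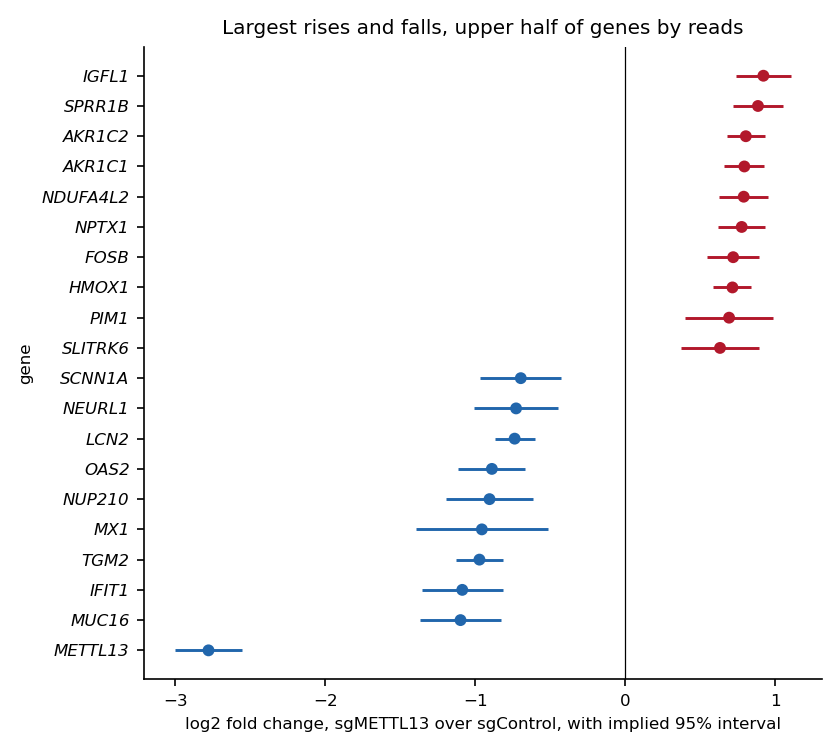
Points give the log2 fold change of sgMETTL13 over sgControl in the authors' deposited table for the 10 largest called rises and 10 largest called falls among genes at or above the median read count, and lines give the implied 95% interval. The rises run from 0.63 in SLITRK6 to 0.92 in IGFL1, and the falls from -0.70 in SCNN1A to -2.78 in METTL13.

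Interferon-stimulated genes, which encode antiviral effectors, fell together. Of 32 measured members of the type I interferon list 18 were lower and none higher in the authors' deposited table (21 and 0 adjusted over the list alone). The median log2 fold change was -0.54 (quartiles -0.95 and -0.22), and the list was shifted down (cameraPR adjusted p = 1.24e-41; 0.00039 with the log2 fold change as the statistic of the test). The RNA sensor DDX58 fell by 0.67, IFIT1 by 1.09, and the oligoadenylate synthetase family members OAS2 and OASL by 0.89 and 0.63 on the log2 scale in the authors' deposited table. In the authors' deposited table the members ISG15 (-0.08), BST2 (0.12) and IFITM3 (0.03), named for their high abundance after their values were seen, did not pass the test. The MHC class I list, whose genes interferon also induces, was not called (adjusted p = 0.370), but was called lower with the trend in GC content and length removed (median -0.092, adjusted p = 0.0317; 0.0112 to 0.933 over the settings run). Of its 15 measured members ERAP2 (-0.28) and PSMB9 (-0.55) were lower in the authors' deposited table (1 higher and 2 lower adjusted over the list alone), and ERAP2 lost its call with the trend removed.

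Targets of NRF2, the transcription factor of the antioxidant response, rose together. In this list 10 of 24 measured members were higher and none lower in the authors' deposited table (14 higher and 1 lower adjusted over the list alone). The median log2 fold change was 0.21 and the cameraPR adjusted p was 9.59e-29. In the authors' deposited table AKR1C2, AKR1C1 and AKR1C3 rose by 0.80, 0.79 and 0.59, HMOX1 by 0.72, and the ferritin heavy chain gene FTH1 by 0.40, from a mean of 9998 to 12565 TPM. The AKR1C genes are related copies that share reads, so the division of reads among them is uncertain.

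Genes induced downstream of RAS and ERK rose as well. Of 31 measured members 13 were higher and none lower in the authors' deposited table (18 and 0 adjusted over the list alone). The median was 0.22 and the cameraPR adjusted p was 2.92e-20. They included the EGF receptor ligand HBEGF (0.52), the ERK phosphatase DUSP6 (0.62), IER3 (0.49) and the immediate-early transcription factor EGR1 (0.59) in the authors' deposited table. ATF4 targets of the integrated stress response, which is set off by amino acid shortage and other stresses, gave 12 higher and none lower of 35 in the authors' deposited table (14 and 0 adjusted over the list alone). The median was 0.17 and the cameraPR adjusted p was 7.93e-18, and 8 members were called with the trend in GC content and length removed. PPP1R15A, the phosphatase subunit that reverses eIF2 phosphorylation, rose by 0.52, GDF15 by 0.54, CEBPB by 0.53 and STC2 by 0.34 in the authors' deposited table. ATF4 itself (0.14), and ASNS (0.17) and DDIT3 (0.27) among its best known targets, named after their values were seen, did not pass the test over all genes in the authors' deposited table; adjusted over the list alone, ATF4 and ASNS passed and DDIT3 did not. With the log2 fold change as the statistic of the test, the NRF2, RAS-ERK and ATF4 lists were not called (adjusted p = 0.371, 0.371 and 0.669).

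Basal-like pancreatic cancer genes were shifted up by a median of 0.13 (cameraPR adjusted p = 8.77e-11). Of 28 measured members 9 were higher and none lower in the authors' deposited table (11 and 0 adjusted over the list alone). SPRR1B (0.89), the keratin KRT14 (0.42), S100A2 (0.40) and LY6D (0.48) led this list in the authors' deposited table. In all, 13 of its members share reads with other genes. Of 22 measured classical-subtype genes, with a median of 5.14 mean reads, FOXA2 rose (0.57 in the authors' deposited table; 1 higher and 1 lower adjusted over the list alone). The classical list was not called (adjusted p = 0.701), and its median lay just below 0 while its mean statistic lay above. Hypoxia and glycolysis genes were shifted up by a median of 0.10 (cameraPR adjusted p = 1.37e-07). Of 30 measured members 3 were higher and none lower in the authors' deposited table (9 and 0 adjusted over the list alone), namely NDRG1 (0.45), BNIP3 (0.36) and PKM (0.16); with the trend in GC content and length removed PKM fell to 0.095 and was no longer called. In the same setting the median of the hypoxia list was 0.046 and that of the basal-like list 0.087, and both stayed called. With the log2 fold change as the statistic both lost the call (adjusted p = 0.898 and 0.386).

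Proliferation genes were shifted down by a small amount. Of 40 measured S-phase and G2/M genes 5 were lower and none higher in the authors' deposited table (9 and 0 adjusted over the list alone). The median was -0.12 and the cameraPR adjusted p was 4.54e-08. The called falls in the authors' deposited table included the DNA methylation maintenance factor UHRF1 (-0.52), CENPF (-0.31) and the replicative helicase subunits MCM6 (-0.33) and MCM2 (-0.27). Fatty acid synthesis genes gave 2 lower and none higher of 13 in the authors' deposited table (5 and 0 adjusted over the list alone). The median was -0.072 and the cameraPR adjusted p was 3.77e-05. The members called were ACLY (-0.25), which makes cytosolic acetyl-CoA, and the elongase ELOVL6 (-0.45) in the authors' deposited table. Neither the proliferation nor the fatty acid list was called with the log2 fold change as the statistic (adjusted p = 0.815 and 0.933).

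**Figure D3:**
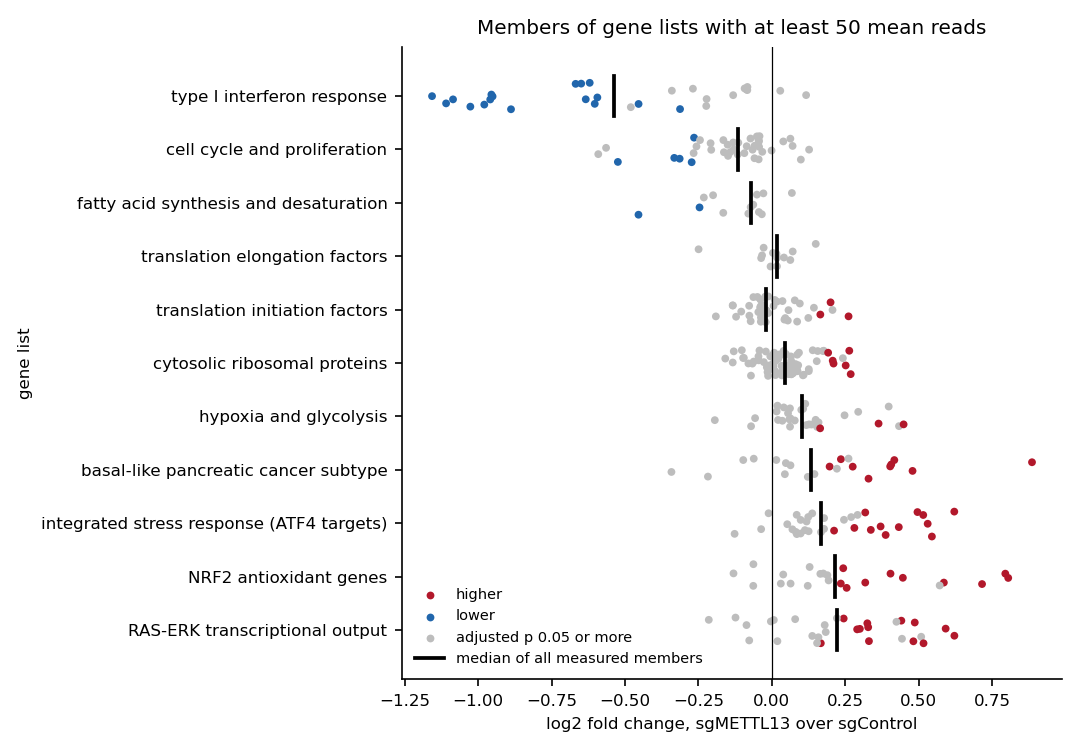
Each point is a member of a gene list with at least 50 mean reads, placed by its log2 fold change of sgMETTL13 over sgControl in the authors' deposited table, in red or blue where the adjusted p is under 0.05; black bars give the median of all measured members of the list. Interferon genes have a median of -0.54, NRF2 and RAS-ERK genes have medians of 0.21 and 0.22, and translation elongation factors lie around 0.016.

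Few genes of the translation machinery were called. None of 14 elongation and termination factors was called in the authors' deposited table, and 1 of them, EIF5A at 0.15, passed adjusted over the list alone. The median of this list was 0.016 and its cameraPR adjusted p was 0.577. Of 22 aminoacyl-tRNA synthetase genes 0 were called in the authors' deposited table or adjusted over the list alone (adjusted p of the list = 0.647). Of 28 tRNA wobble-base modification enzymes 0 were called in the authors' deposited table, with 2 higher and 2 lower adjusted over the list alone (adjusted p of the list = 0.643). Among 40 genes for initiation factors and their inhibitors, EIF1 (0.26), the inhibitor EIF4EBP1 (0.20) and EIF3B (0.16) were higher in the authors' deposited table and adjusted over the list alone. With the trend in GC content and length removed, EIF4EBP1 (0.055) and EIF3B (0.11) lost the call. That list was not called by cameraPR (adjusted p = 0.665), and its median of -0.020 lay below 0 while its mean statistic lay above. The median lay at percentile 0.46 of random lists matched on read count. Cytosolic ribosomal protein genes had 6 of 78 higher and none lower in the authors' deposited table (10 and 0 adjusted over the list alone), led by RPS26 (0.26), RPL27 (0.27), RPS14 (0.25) and RPL13A (0.21). Their median of 0.045 lay at percentile 10.1 of random lists matched on read count although cameraPR called them up (adjusted p = 0.00183). The call of the list was lost with the trend in GC content and length removed (adjusted p = 0.987). It was also lost at a correlation of 0.1 between genes (adjusted p = 0.312). With the trend removed 2 members were called higher, RPS26 and RPS14, while RPL27 and RPL13A lost the call.

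Several further lists were called with adjusted p values closer to the threshold. Heat shock genes had a median of -0.10 and a cameraPR adjusted p of 0.00754 with 0 of 18 members called in the authors' deposited table and none adjusted over the list alone; with the trend in GC content and length removed 2 were called lower, HSPA1A (-0.23) and HSPA1B (-0.23), and the list stayed called. MYC-driven growth genes (median -0.065, adjusted p = 0.0398) had 1 higher, the ornithine decarboxylase gene ODC1 (0.60), and 2 lower, TRAP1 (-0.21) and PAICS (-0.17), of 30 in the authors' deposited table (1 and 4 adjusted over the list alone). The 25 measured cholesterol synthesis genes had a median of -0.039 and a cameraPR adjusted p of 0.0228. Replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails and so serve as a sign of how RNA was selected for the libraries, had a median of 0.29 and an adjusted p of 0.0224, with HIST1H1C (0.48) and HIST1H2AC (0.41) higher of 40 in the authors' deposited table and adjusted over the list alone, at a median of 6.83 mean reads per gene. Neither gene was called with the trend in GC content and length removed, while the list stayed called. At a correlation of 0.1 between genes these 4 lists were no longer called, with adjusted p values of 0.149 for heat shock, 0.384 for MYC, 0.312 for cholesterol synthesis and 0.384 for histones.

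Lists that cameraPR did not call still held single changes. Of the genes named for them here, PLK3, RELB, UQCR11 and F3 lost the call with the trend in GC content and length removed. The p53 list (adjusted p = 0.0746) had CDKN1A (0.47), TNFRSF10B (0.27) and PLK3 (0.33) higher of 23 in the authors' deposited table and adjusted over the list alone. The unfolded protein response list (adjusted p = 0.149) had XBP1 higher (0.28) of 22 in the authors' deposited table and adjusted over the list alone. NF-kB and cytokine genes (adjusted p = 0.577) had 4 higher, among them CSF3 (0.69), IL1A (0.28) and RELB (0.29), and LCN2 lower of 24 in the authors' deposited table (7 and 2 adjusted over the list alone). TGF-beta and mesenchymal genes (adjusted p = 0.460) went both ways. In the authors' deposited table TGFB1 (0.38) and the integrin ITGA5 (0.33) were among 5 higher, and TGFBI (-0.24) and TGFB2 (-0.38) among 3 lower of 29. Adjusted over the list alone 6 were higher and 5 lower. With the trend in GC content and length removed 3 were higher and 4 lower. YAP/TEAD targets (adjusted p = 0.577) had TGFB2, IGFBP3 (-0.34) and F3 (-0.15) lower of 25 in the authors' deposited table (2 higher and 6 lower adjusted over the list alone). Their median of 0.051 lay above 0 and their mean statistic below. Of 28 epithelial junction genes (adjusted p = 0.415) TJP3 was lower (-0.55) in the authors' deposited table and adjusted over the list alone, and with the trend in GC content and length removed the list was called lower (median -0.073, adjusted p = 0.0372; 0.00253 to 0.937 over the settings run). Of 63 nuclear-encoded respiratory chain genes (adjusted p = 0.0856) UQCR11 was higher (0.25) in the authors' deposited table, and 0 were called adjusted over the list alone. Of the markers of other cell types, none of 6 fibroblast, 4 immune, 7 endothelial and 6 acinar or islet genes was called in the authors' deposited table. Adjusted over the list alone, the endothelial gene CLDN5 was higher (1.09 in the authors' deposited table, from 19.3 to 39.7 mean reads). These lists had cameraPR adjusted p values of 0.905, 0.665, 0.753 and 0.460 (the acinar and islet list was called higher, at 0.00039, with the log2 fold change as the statistic), and the highest mean TPM among their members was 44.1, for CD68.

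The fold changes and adjusted p values are those of the authors' comparison, and nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p values measure the spread between these libraries, which may be technical. The cameraPR tests assume a correlation of 0.01 between genes of a list, and which of the 14 calls would hold with an estimated correlation could not be determined without values per library; at a correlation of 0.1 there were 9. With the log2 fold change as the statistic 13 of the 14 calls were lost, and the interferon list stayed called.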

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

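The trend, shared-read and higher-correlation settings were chosen after the data were seen. No paired analysis was possible because the table gives averages over the libraries of each group. For the same reason DESeq2 against edgeR, size factors against TMM, the pseudocount of 0.1, leaving out each library, the estimated correlation and other splits of the libraries were not run; the count with no filter is the main one. METTL13 stayed between -2.83 and -2.78 under every setting run. Against 632 calls, an adjusted p under 0.01 left 409 (104 lower), and one under 0.1 gave 269 lower. A log2 fold change of at least 1 left 14, of which 3 were higher and 11 lower (21.4% higher), and at least 0.5 left 110, with 55 each way (50% higher). Bonferroni left 180, 136 higher and 44 lower. These follow from stricter or looser thresholds. With the GC and length trend removed there were 263 higher calls (60.7% of calls), of which 236 were among the 453 as reported, so that 217 were lost and 27 were new. With read count added to the trend there were 400 calls with 226 higher (56.5%). The 453 rises as reported had a median log2 fold change of 0.31, and of 0.24 once the GC and length trend was removed. Centring, a filter at the median read count, recomputed adjustment and leaving out shared reads gave 559 to 776 calls. Of 31 lists, 14 were called as reported. Under the rank-based test, the filter, the trends and without shared reads 11 to 16 were called. With the filter and without shared reads, fewer than 31 lists kept enough genes to be tested. At a correlation of 0.1 there were 9 calls. With the log2 fold change as statistic, which gives genes with few reads the same weight as abundant ones, there were 2. In that setting 13 of the 14 lost the call (adjusted p from 0.371 to 0.933), the interferon genes stayed called and the acinar and islet markers gained a call (0.00039 each). Ribosomal proteins reversed to lower with GC, length and read count removed (adjusted p = 0.00471); the cause was not tested. Of the named genes 117 kept their side of the threshold with the GC and length trend removed, 13 lost the call (RPL27, RPL13A, HIST1H1C, HIST1H2AC, PKM, RELB, PLK3, EIF4EBP1, EIF3B, UQCR11, F3, ERAP2 and PAICS) and 4 gained it. Of the lists in the same setting 28 kept it, 2 gained a call (MHC class I and epithelial junction genes) and 1, the ribosomal proteins, lost it.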

Other observations

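Gene families chosen after their values were seen, counted over members with at least 50 mean reads, overlap in part with the fixed lists (DUSP4, DUSP5, DUSP6 and FOSL1 are in the RAS-ERK list and S100A2 in the basal-like list). Among AP-1 subunits, which form an immediate-early transcription factor, 3 of 7 were higher in the authors' deposited table, FOSB (0.72), JUNB (0.47) and FOSL1 (0.33). The dual-specificity phosphatases, several of which dephosphorylate MAP kinases, had 5 of 16 higher (4 with centred fold changes), including DUSP6 (0.62) and DUSP1 (0.61) in the authors' deposited table. Of 9 S100A calcium-binding protein genes 6 were higher (4 with the GC and length trend removed), among them S100A2 (0.40), S100A10 (0.37) and S100A11 (0.33) in the authors' deposited table. Syndecans, cell-surface heparan sulfate proteoglycans, had SDC4 (0.46) and SDC1 (0.42) higher of 4 in the authors' deposited table, and Kruppel-like factors had KLF6 (0.42), KLF4 (0.35) and KLF5 (0.20) higher of 12 (5 with the trend removed).

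Of 6 mucin genes MUC4 (-1.32), MUC16 (-1.10) and MUC1 (-0.46), which encode membrane mucins, were lower and none higher in the authors' deposited table. Outside the interferon list, the antiviral pair SAMD9 (-0.60) and SAMD9L (-1.36) and the PARP family members PARP9 (-0.46) and PARP14 (-0.44), all interferon-induced genes, were lower in the authors' deposited table, as was PARP1 (-0.41). The 3 called PARP genes were among 11 measured. Ceruloplasmin (CP), the plasma ferroxidase, named after its value was seen, fell from 87 to 24 mean reads in the authors' deposited table, a log2 fold change of -1.80 that is the largest called fall after METTL13. Of the genes within 1 Mb of METTL13 on chromosome 1, which lie outside the rule for named genes and were chosen after their values were seen, SUCO was lower (-0.37, adjusted p = 0.0274) in the authors' deposited table, while PRRC2C (-0.12), VAMP4 (-0.04), DNM3 (-0.07) and PIGC (-0.24) did not pass the test.

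Patterns were weighed with tests, of which the test of a divergent library was chosen after the result was seen; the trend and shared-read settings themselves were chosen after the data were seen. The fall of the type I interferon genes kept a median of -0.52 with the trend in GC content and length removed, which argues against that trend as its cause. If 1 divergent library carried the fall, its genes would vary more within a group than other genes of the same read count; the median relative implied standard error of 29 members was 1.08 (quartiles 1.01 and 1.16, with MX1 as the 1 member above 1.5), against quartiles of 0.97 and 1.04 over 10884 genes. The upper quartile of the members lay at the 95th percentile over all these genes (1.158 for each). The members thus varied more than most genes of their read count, by a small factor at the median and more clearly in the upper part of the list. Without values per library a share of 1 divergent library in the fall cannot be told apart from a fall in each library. A difference between the cell populations that arose after guide delivery could not be examined, since the labels name 1 guide condition per group.

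The excess of rises over falls among the called genes went with the GC content and length of transcripts and with read count. In genes at or above the median read count the median log2 fold change went from -0.048 in the fifth with the lowest GC content to 0.091 in the fifth with the highest, where 182 genes were higher and 10 lower; across genes Spearman's rho was 0.36 with GC content, -0.25 with transcript length and 0.22 with mean reads (219 higher and 24 lower in the fifth with the most reads), and genes are not independent replicates. Centring the fold changes by 0.011, their median in genes at or above the median read count, left 66.6% of calls higher. A scaling shift of that size does not account for the excess. A larger shift, such as the median of 0.055 in the fifth with the most reads, was not tried on its own. The fold changes already carried the 0.0516 added by the authors' scaling, and the part of that scaling in the excess was not weighed. With the GC and length trend removed 60.7% of calls were higher, between the bounds set in advance for and against that trend as the cause. Since that removal also centred the fold changes on their weighted mean, the change in the share is not due to GC content and length alone. With read count added to the trend 56.5% were higher, below the bound that had been set for GC content and length alone. The relative implied standard error of the genes richest in GC was 1.03, between the bounds set for a GC bias that differs between libraries. Whether the trend arose in the libraries or in the cells cannot be told apart here. The histone list, fixed as a sign of how RNA was selected for the libraries, was called higher by cameraPR (median 0.29 at a median of 6.83 mean reads per gene), but 2 of its 40 members were called in the authors' deposited table and none with the trend removed, and the list was not called at a correlation of 0.1 between genes (adjusted p = 0.384) or with the log2 fold change as the statistic (0.371). A difference in RNA selection between the groups stays open and was not tested.

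The rise of the stress response, ERK, NRF2 and basal-like lists was weighed against the same trend and against reads shared by paralogs. With the GC content and transcript length trend removed 4 of the 4 lists stayed called. As a test of reads shared between paralogs, genes that share reads were left out, and 4 of the 4 lists stayed called. Neither accounts for the rise as a whole. The 4 lists were not called with the log2 fold change as the statistic of the test (adjusted p from 0.371 to 0.669), where genes with few reads weigh as much as abundant ones. A difference between the cultures of the groups, such as density, stays open and was not tested.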
